A study of Mus musculus with 25 samples.

How the data were processed

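Bulk RNA-seq of mouse liver was analysed from 2 experiments, natural aging with 9 libraries and hepatocyte-specific Cisd2 knockout with 16. Per the labels' protocols, total RNA was extracted with TRIzol and stranded mRNA libraries were made from 4 µg of RNA with the TruSeq Stranded mRNA kit in the aging batch and from 1 µg with the Stranded mRNA Prep Ligation kit in the knockout batch. The batches were therefore fitted separately, and only fold changes were compared between them. Groups were taken from the labels' ages, genotypes and treatments. The old group follows the submitters' design text, which names young, old and old treated mice, and so it joins an untreated mouse with mice given vehicle, while the young mice received nothing.

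The authors deposited expected counts per gene, estimated counts that need not be whole, and 28.8% of the values in the aging table and 34.4% in the knockout table were not whole. The deposited normalized count tables hold a signal made by the authors from the same values: with a tolerance of 0.1, 100% of the values equalled the whole part of the expected count divided by 1 factor per library. These tables served only for that check. The deposited tables list a gene only where it reaches 100 expected counts in at least 3 libraries (aging) or 8 libraries (knockout), as read from the values, so weakly expressed genes, among them all members of the T and NK cell list and all but 1 exocrine pancreas gene, were not analysed here. In the aging table this floor admits a weakly expressed gene more readily where it is high in 1 group. Markers of cell types with few cells are among such genes. The 8 libraries asked for in the knockout table are more than 1 group holds. A gene that reaches 100 expected counts in only 1 group is therefore not listed there. Per the submitters' processing notes the genome build was GRCm38 (mm10) and DESeq2 was used, with no versions. The aligner, counter, annotation and strand setting are not given in the sources used here. Reads from near-identical genes can have been divided between copies, and values of such families are called uncertain.

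Gene identifiers were those of the tables. GENCODE M21 (GRCm38) held 10209 of 10224 identifiers in the aging table and 9890 of 9935 in the knockout table and gave the coordinates, while 4 and 32 listed genes had no symbol. All 33 pairs of replicates within groups differed by more than sampling noise (lowest chi-square per degree of freedom 15.5), so each library counted as 1 sample. No columns were left unused (0 columns of per-sample values).

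Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, which removed 0 genes from either table, and quasi-likelihood F tests in 1 fit per experiment over all its groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 0.184 in the aging and 0.126 in the knockout experiment. Standard errors were the absolute log2 fold change over the square root of F. The comparisons, 7 in all, were old against young, PZ19b in old, hKO against f/f with vehicle and with PZ19b, PZ19b in f/f, PZ19b in hKO and the interaction of PZ19b with genotype. CPM values used TMM library sizes.

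Designs, alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The 43 lists name pathways, cell types and liver functions, and 678 of their 880 members (77.0%) were measured in the aging table and 648 (73.6%) in the knockout table. The 39 lists per comparison with at least 3 measured members, study genes and sex chromosome genes aside, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Member calls were counted with adjustment over all genes and adjusted over the list alone. Camera with a correlation estimated per list passed 0 lists in all 7 comparisons, and its adjusted p stands beside each list. Some genes belong to more than 1 list, Hmgcs2 to the PPARα and ketogenesis lists among them.

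Named genes were, per comparison, the 10 that rose and the 10 that fell most among called genes with a mean of at least 1 CPM, no overlap between the groups (not asked of the interaction) and a symbol other than a predicted gene. In each list described the 4 measured members with the smallest p were eligible, and Cisd2, Hmgcs2 and Ppara were always named. Reversal and shared response were measured across genes, beside values from 100 simulations or from other splits of the libraries. Each simulation drew all libraries of the groups anew, the treated group from its own control so that it was unchanged. A simulated library was a group mean plus or minus the scaled deviation of 1 real library, drawn with replacement. Simulated replicates could thus be copies or mirror images of each other, so shares of simulations are rough.

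Alternatives were DESeq2 1.42.0, DESeq2 (RLE) size factors, no low count filter, the replicate number as a block, only the compared groups in the fit and each replicate left out in turn. After the data were seen, counts reduced to their whole parts, library totals without TMM, vehicle old against PZ19b mice of 26 months, and f/f groups without the 3 libraries with the highest acute phase genes (vehicle replicates 2 and 3, PZ19b replicate 1) were added, as was the pair of PZ19b in f/f with PZ19b in hKO.

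The steps were tested on simulated counts drawn from the real means and library sizes. For old against young 23.9% of 67 genes changed 1.5-fold, 88.1% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered, and 0.110% of 10003 unchanged genes were called. For hKO against f/f with vehicle the shares were 68.7%, 94.0% and 100%, and 0.0515% of 9713 unchanged genes were called. A list with moved members was called in both, and 0 of 28 and 0 of 22 lists without changed members were. Simulated genes were drawn independently of each other, so this says nothing about false list calls where members are correlated. Few simulated genes changed and all groups had the same spread, unlike in the real data, so the recovered shares are rough.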

Results

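Liver RNA was profiled by stranded mRNA sequencing in 2 mouse experiments, and expected counts per gene were analysed. The natural aging experiment held 9 wild-type libraries in 3 groups of 3. Young mice were 3 months old and untreated. The old group held an untreated mouse of 26 months (replicate 1) and mice of 26 and 27 months given a 10% PG vehicle for 5 months (replicates 2 and 3). The old PZ19b group held mice of 26, 26 and 32 months given PZ19b for 5 months, which is taken from the design text to be hesperetin, a citrus flavanone. The knockout experiment held 16 libraries from mice of 6 months, with 4 in each of 4 groups. Floxed Cisd2 controls (f/f) and mice lacking Cisd2 in hepatocytes (hKO) received vehicle or PZ19b for 3 months. Total expected counts per library ran from 21569489 to 27534791 in the aging experiment, over 10224 listed genes, and from 20726900 to 27821500 in the knockout experiment, over 9935 listed genes. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples. All changes below are log2 fold changes, and values after ± are SE unless named SD, with n = 3 per group in the aging experiment and n = 4 per group in the knockout experiment.

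The knockout was checked first through Cisd2 (ENSMUSG00000028165, chromosome 3, 135406412 to 135423925 on the minus strand, GRCm38), which encodes an iron-sulphur protein of the endoplasmic reticulum (ER) and outer mitochondrial membranes. Cisd2 stood at 24.7 ± 1.82 CPM (SD, n = 4) in f/f vehicle livers, with single libraries from 22.4 to 26.9, and at 25.6 ± 1.35 CPM (SD, n = 4) in f/f PZ19b livers, from 24.8 to 27.6. The hKO vehicle libraries held 4.66 ± 0.371 CPM (SD, n = 4), from 4.22 to 4.99, and the hKO PZ19b libraries 4.49 ± 0.262 CPM (SD, n = 4), from 4.28 to 4.86. Every hKO library thus lay below every f/f library, at 18.9% of the control mean with vehicle and 17.5% with PZ19b. The fall was −2.40 ± 0.08 with vehicle (edgeR adjusted p = 2.26e-11) and −2.51 ± 0.08 with PZ19b (edgeR adjusted p = 1.14e-11).

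Whether Cisd2, Hmgcs2 and Ppara moved with age or with PZ19b follows from the series title, which links these genes to liver aging. In the aging experiment Cisd2 stood at 46.2 ± 3.08 CPM (SD, n = 3) in young, 43.6 ± 1.09 in old and 42.9 ± 2.80 in old PZ19b livers. Its difference was −0.08 ± 0.08 for old against young (edgeR adjusted p = 0.471) and −0.02 ± 0.08 for PZ19b in old mice (edgeR adjusted p = 0.866). PZ19b gave Cisd2 differences of 0.05 in f/f and −0.06 in hKO livers, neither past the threshold (edgeR adjusted p = 0.689 and 0.753). Differences this small changed sign in some alternatives. With library totals and no TMM factor the old against young value was 0.21, and without PZ19b replicate 3 the value for PZ19b in old mice was 0.03.

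Hmgcs2 (ENSMUSG00000027875, chromosome 3, 98280435 to 98310738 on the plus strand, GRCm38), the rate-limiting mitochondrial enzyme of ketone body synthesis, rose with PZ19b in old livers by 0.82 ± 0.18 (edgeR adjusted p = 0.0355). It stood there at 2427 ± 198 CPM (SD, n = 3), against 1378 ± 306 in old and 1785 ± 132 in young livers. The old against young difference of −0.37 ± 0.18 did not pass the test (edgeR adjusted p = 0.153). In the knockout experiment PZ19b gave 0.23 ± 0.11 in f/f and 0.37 ± 0.11 in hKO livers (edgeR adjusted p = 0.225 and 0.0595), and the interaction was 0.14 ± 0.16 (edgeR adjusted p = 0.625). Under PZ19b, Hmgcs2 was higher in hKO than in f/f livers by 0.34 ± 0.11 (edgeR adjusted p = 0.0323). The call in old mice was lost without old replicate 2 (edgeR adjusted p = 0.125) or PZ19b replicate 1, 2 or 3 (0.0835, 0.0539 and 0.0965), and over all alternatives its adjusted p ran from 9.80e-05 to 0.129. Without old replicate 3, old against young passed at −0.54 (edgeR adjusted p = 0.0485). The call under PZ19b was lost without f/f PZ19b replicate 1, 2 or 4 or hKO PZ19b replicate 2, 3 or 4, with adjusted p from 0.0572 to 0.0879.

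Ppara (ENSMUSG00000022383, chromosome 15, 85734983 to 85802819 on the plus strand, GRCm38), the nuclear receptor that drives fatty acid oxidation genes, rose with PZ19b by 0.56 ± 0.14 in f/f livers and by 0.50 ± 0.14 in hKO livers (edgeR adjusted p = 0.0218 and 0.0415). Mean CPM went from 115 ± 19.6 to 169 ± 24.8 in f/f and from 137 ± 20.8 to 193 ± 25.5 in hKO livers (SD, n = 4). In old mice the PZ19b difference of 0.86 ± 0.25 missed the threshold (edgeR adjusted p = 0.0678), as did old against young at −0.43 ± 0.25 (edgeR adjusted p = 0.236). The 3 old libraries spread widely, with a mean of 107 ± 42.2 CPM (SD, n = 3), against 144 ± 2.11 in young and 194 ± 8.11 in old PZ19b livers. The f/f call was lost without f/f vehicle replicate 1 or 2 or PZ19b replicate 2 or 3, with adjusted p from 0.0511 to 0.0753, and the hKO call without hKO vehicle replicate 1 or 2 or any PZ19b replicate, with adjusted p from 0.0608 to 0.129. In old mice the PZ19b difference passed without old replicate 1 or 3 (0.59 and 1.17, edgeR adjusted p = 0.0242 and 0.0142), and old against young passed without old replicate 3 (−0.73, adjusted p = 0.0334).

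**Figure D1:**
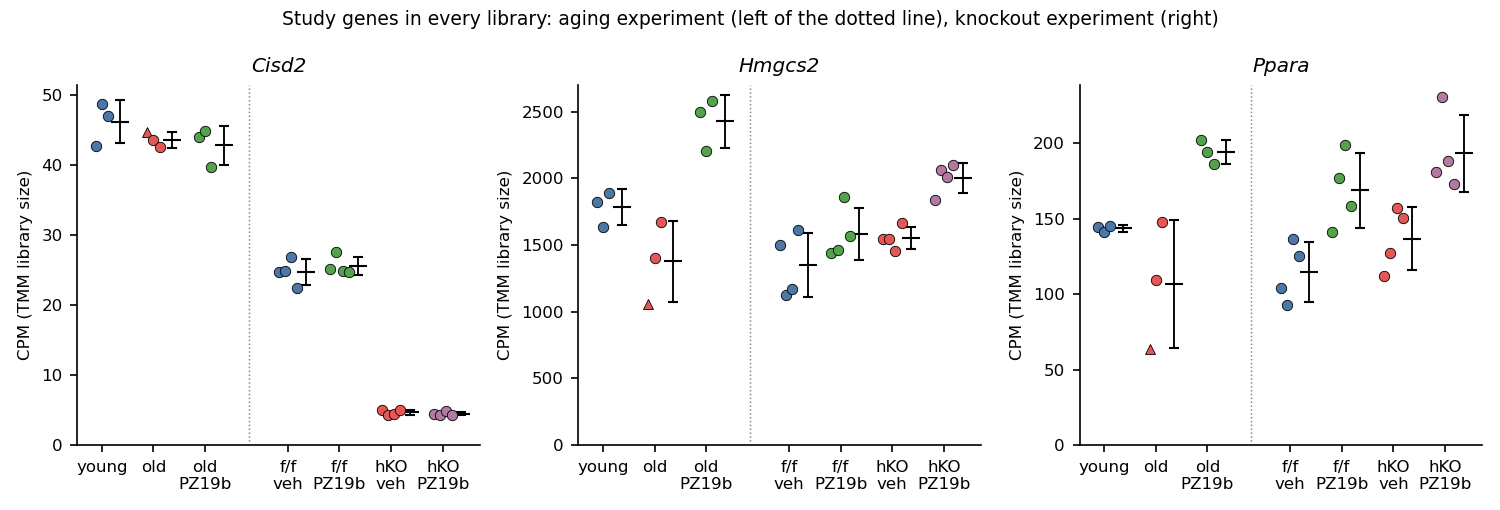
Normalised CPM of Cisd2, Hmgcs2 and Ppara in each library by group, with the group mean and SD. Cisd2 lies between 4.22 and 4.99 CPM in hKO vehicle libraries and between 22.4 and 26.9 in f/f vehicle libraries, and Hmgcs2 averages 2427 CPM in old PZ19b livers against 1378 in old livers, where the triangle marks the untreated mouse.

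Aging was asked about by comparing old with young livers. Many genes with sex-dependent liver expression changed. The Y chromosome genes Ddx3y, Uty, Kdm5d and Eif2s3y were expressed in every young and old library. Their lowest values were 81.2, 16.6, 20.8 and 51.6 CPM in old livers and 101, 17.5, 19.6 and 55.3 CPM in young livers. Xist was not among the listed genes. These values argue against female livers in the old group as the source of the sex-dependent changes. Hsd3b5, a male-specific steroid dehydrogenase, fell by 8.49 ± 1.06, the organic anion transporter Slco1a1 changed by −6.89 ± 0.60 and Selenbp2 by −5.44 ± 0.35. Of 17 measured male-biased liver genes 15 fell, 17 adjusted over the list alone, with a median of −2.87. The camera adjusted p was 1.42e-11, and adjusted p = 0.333 with an estimated correlation. Female-biased liver genes went the other way, and 5 of the 6 measured rose, also 5 adjusted over the list alone, with a median of 2.79. Most members of this list lay under the tables' floor. The floor more readily admits a gene that is high in 1 group, so this share is partly built in. Cyp17a1, a steroid hydroxylase, rose by 6.65 ± 1.25, the oxygenase Fmo2 by 2.11 ± 0.31 and the acyl-CoA thioesterase Acot3 by 3.48 ± 0.75. That list had a camera adjusted p = 0.00129, and adjusted p = 0.333 with an estimated correlation. The hydroxylase gene Cyp2a22 rose by 7.44 ± 1.15 and the transporter gene Slc22a27 by 8.13 ± 1.08, while Slc22a28 changed by −6.88 ± 0.60 and Ugt2b38 by −6.89 ± 0.64. Near-identical copies exist for Ugt2b, Cyp2a, Acot and Slc22a members, so reads could be split between them and their values are uncertain.

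Genes of immune and matrix-producing cells were higher in old livers. Of 22 measured genes of the stellate cells and fibrosis list 20 rose, 21 adjusted over the list alone, with a median of 1.67. Col5a2, a fibrillar collagen chain, rose by 2.93 ± 0.35, the stellate receptor Pdgfrb by 1.45 ± 0.20 and the proteoglycan Dcn by 0.74 ± 0.10. Camera gave this list an adjusted p = 3.11e-08, and adjusted p = 0.467 with an estimated correlation. All 6 measured genes of the B cell and plasma cell list, which has 20 members, rose, 6 also adjusted over the list alone, with a median of 4.78. Igkc and Ighm, immunoglobulin chains whose counts are uncertain among related genes, rose by 4.91 ± 0.35 and 4.66 ± 0.39, and Jchain by 4.12 ± 0.51 (list camera adjusted p = 3.75e-06, and adjusted p = 0.333 with an estimated correlation). Kupffer cell markers rose in 9 of 12 cases, 10 adjusted over the list alone, led by the scavenger receptor Marco at 3.65 ± 0.25 (camera adjusted p = 0.000139, and adjusted p = 0.467 with an estimated correlation). Markers of recruited myeloid cells rose in 6 of 6 cases by either adjustment, with Lyz2, a lysozyme, at 2.03 ± 0.28 and Ccr2, a monocyte chemokine receptor, at 2.94 ± 0.53 (camera adjusted p = 0.000876, and adjusted p = 0.467 with an estimated correlation). Sinusoidal endothelial markers, in contrast, had a median of 0.17, with 3 of 17 rising and a camera adjusted p = 0.176. Most members of the B cell and recruited myeloid lists lay under the tables' floor, so their shares of rising genes are partly built in.

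Beside these cell markers, 16 of 30 interferon response genes rose, 18 adjusted over the list alone, with a median of 1.57. The antiviral genes Rsad2, Oas2 and Oas1a rose by 1.85 ± 0.29, 1.77 ± 0.29 and 2.53 ± 0.42 (list camera adjusted p = 4.26e-08, and adjusted p = 0.491 with an estimated correlation). Proliferation genes rose in 7 of 8 cases by either adjustment, with the replication helicase subunits Mcm4 and Mcm3 at 2.01 ± 0.32 and 1.83 ± 0.30 (camera adjusted p = 0.000428, and adjusted p = 0.467 with an estimated correlation). The fetal and tumour-associated liver genes rose in 6 of 6 cases by either adjustment, among them Scd2, a desaturase, at 1.70 ± 0.19 and Golm1, a Golgi protein, at 1.83 ± 0.29 (camera adjusted p = 0.000544, and adjusted p = 0.467 with an estimated correlation). Most members of the proliferation and fetal lists lay under the tables' floor, so their shares of rising genes are partly built in. The rises of the stellate, fetal and proliferation lists were uneven within the old group. The mean log2 deviation of the stellate list was −0.19 in the untreated old library and 1.39 and 1.36 in the vehicle libraries, against a young mean of −0.77. For the fetal list the values were 0.03, 1.37 and 1.65, and for proliferation −0.01, 0.84 and 1.28. Among the p53 targets 6 of 14 rose, 7 adjusted over the list alone, with Btg2, an antiproliferative gene, at 1.33 ± 0.12 (camera adjusted p = 0.000573, and adjusted p = 0.333 with an estimated correlation).

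Metabolic and hepatocyte genes moved in both directions. NRF2 targets, which serve antioxidant and conjugation functions, rose in 11 of 21 cases and fell in 1, or 12 and 1 adjusted over the list alone. The quinone reductase Nqo1 rose by 2.06 ± 0.18, the pentose phosphate enzyme Pgd by 1.44 ± 0.09 and the transporter Abcc4 by 2.24 ± 0.22 (list camera adjusted p = 0.000943, and adjusted p = 0.467 with an estimated correlation). The fatty acid transporter Cd36 rose by 2.47 ± 0.23. In the hepatocyte identity list 8 of 22 genes fell and 1 rose, or 9 and 1 adjusted over the list alone, with the liver transcription factor Foxa3 at −1.24 ± 0.21 and the tryptophan dioxygenase Tdo2 at −1.20 ± 0.22 (camera adjusted p = 0.000876, and adjusted p = 0.467 with an estimated correlation). Cyp2e1, an ethanol-metabolising pericentral enzyme, fell by 1.28 ± 0.21. Of 59 respiratory chain genes 1 was called and the median was −0.19, which became 0.11 with library totals and no TMM factor (camera adjusted p = 0.000132, and adjusted p = 0.678 with an estimated correlation). Without old replicate 3 the nuclear-encoded respiratory chain list lost its call, at 0.0615. PPARα targets split, with 9 of 44 rising and 6 falling, or 10 and 8 adjusted over the list alone. Their median was −0.03, which became 0.27 without TMM, while their mean was 0.30 and the camera direction down (adjusted p = 0.925).

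In all, 1467 genes rose and 1107 fell by edgeR's quasi-likelihood test, 25.2% of those tested, and 587 and 160 of them passed a 2-fold change. The libraries did not overlap for 4642 genes (45.4%, where chance gives 10%), and 21 of 39 gene lists passed camera, none with an estimated correlation, where the lowest adjusted p was 0.333. Without young replicate 1, 2 or 3 the count was 1263, 1135 or 1231, without old replicate 2 it was 1159, and without TMM the median of all genes shifted by 0.30 with 4116 rising and 299 falling, so directions are relative to the median gene.

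**Figure D2:**
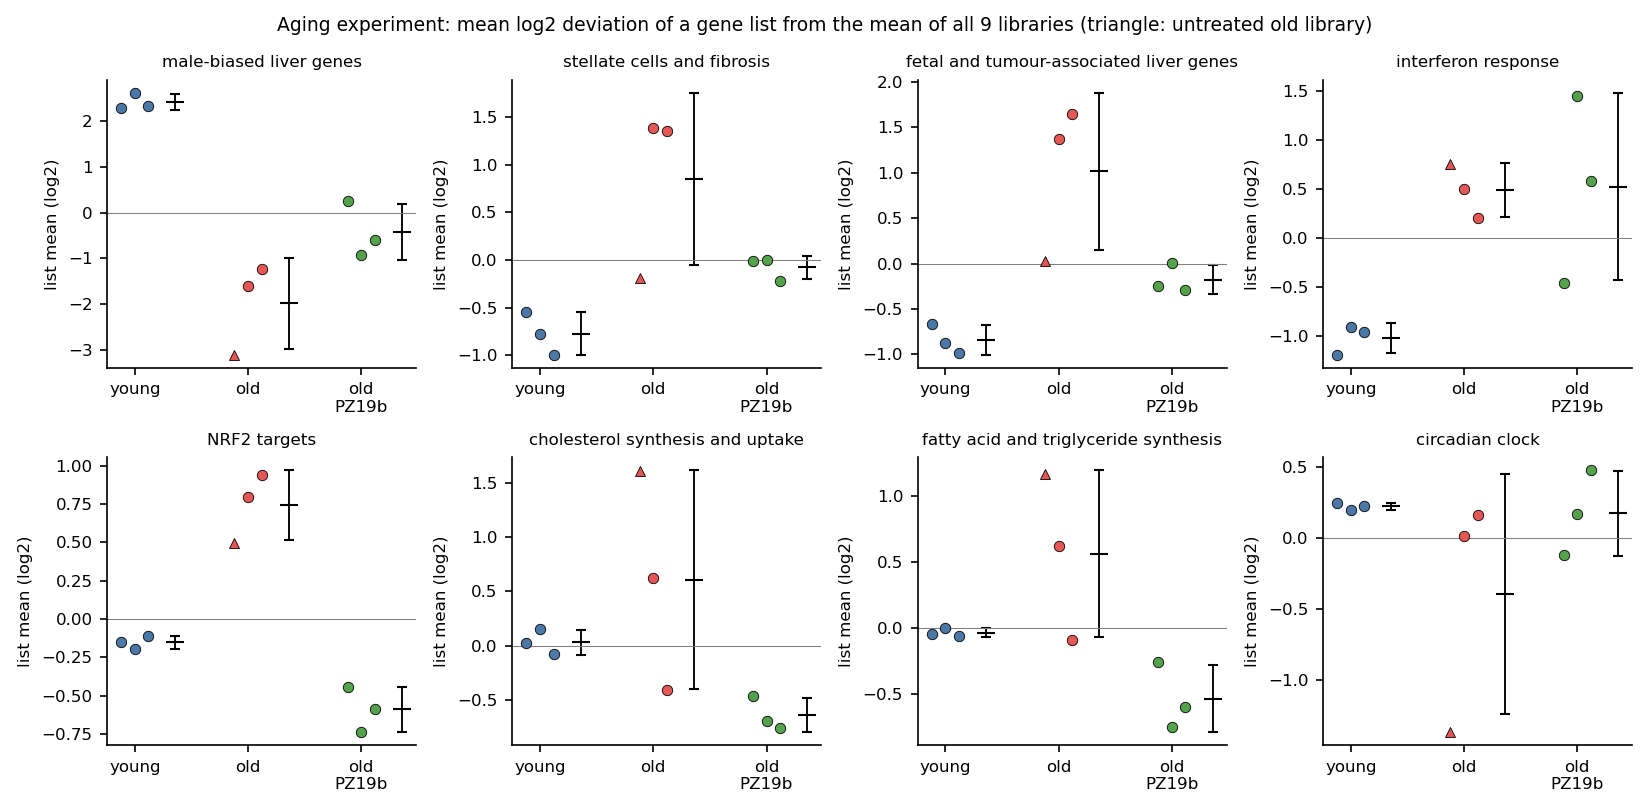
Mean log2 deviation of 8 gene lists in each library of the aging experiment, with the group mean and SD (n = 3). The stellate and fibrosis list lies at −0.19 in the untreated old library, marked by a triangle, and at 1.39 and 1.36 in the vehicle old libraries.

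PZ19b in old mice was set against the old group. Of 21 measured NRF2 targets 14 fell, 16 adjusted over the list alone, with a median of −1.35. Pgd changed by −1.43 ± 0.09, the glutathione transferases Gstm2 and Gstm4 by −2.13 ± 0.22 and −1.72 ± 0.18, and Nqo1 by −1.64 ± 0.18. This list had a camera adjusted p = 3.52e-10, and adjusted p = 0.288 with an estimated correlation, and 12 members still fell when the vehicle old libraries alone were compared with PZ19b mice of 26 months. Some lipid synthesis genes also fell. Of 25 genes of cholesterol synthesis and uptake 9 fell, 16 adjusted over the list alone, with a median of −1.36, and of 20 genes of fatty acid and triglyceride synthesis 7 fell, 11 adjusted over the list alone, with a median of −1.03. Acaca, the acetyl-CoA carboxylase of fat synthesis, fell by 1.41 ± 0.16. Camera gave cholesterol genes an adjusted p = 1.15e-07 and fatty acid genes 3.04e-05, and both had adjusted p = 0.612 with an estimated correlation. With the vehicle old libraries alone as reference for PZ19b mice of 26 months, 4 cholesterol and 3 fatty acid genes fell, with medians of −0.61 and −0.80. The untreated old library held the highest cholesterol list mean, 1.61, against 0.62 and −0.41 in the vehicle old libraries.

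Cyp2c54 rose with PZ19b in old livers by 3.87 ± 0.25, Cyp2c23, an arachidonic acid epoxygenase, by 2.33 ± 0.10 and the carboxylesterase Ces3a by 2.23 ± 0.15. Mup3, a major urinary protein, rose by 2.31 ± 0.18, and like Cyp2c54 and the Gstm genes it has close copies that leave its count uncertain. The male-biased transporter Slco1a1 rose by 4.55 ± 0.54 and the pericentral enzyme Cyp2e1 by 1.60 ± 0.21. The pericentral hepatocytes list had 4 of 14 genes rising, 5 adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.612 with an estimated correlation), a call lost without old replicate 3 at 0.181. Of 44 PPARα targets 4 rose and 1 fell, or 5 and 1 adjusted over the list alone, with a median of 0.20 and a camera adjusted p = 0.0103, which was 0.749 with an estimated correlation. Cyp4a10, a fatty acid hydroxylase, stood at 1.16 ± 0.26 and the thiolase Acaa2 at 0.51 ± 0.11. The PPARalpha targets list lost its call without old replicate 1, the untreated library, at a camera adjusted p = 0.250. It lost the call as well when the vehicle old libraries alone were compared with PZ19b mice of 26 months. Cyp4a10 and Acaa2 lost theirs without old replicate 2 (adjusted p = 0.127 and 0.119) or PZ19b replicate 1, 2 or 3.

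Stellate, fetal liver and proliferation genes were high in the vehicle old libraries, which also belong to the reference for PZ19b. In the stellate cells and fibrosis list 3 of 22 fell, 12 adjusted over the list alone, with a median of −1.03 (camera adjusted p = 0.000456, and adjusted p = 0.626 with an estimated correlation). The collagen chain Col5a2 stood at −1.79 ± 0.33 and Sparc, a matrix glycoprotein, at −1.20 ± 0.26. When the vehicle old libraries alone were compared with PZ19b mice of 26 months, 14 of the 22 fell with a median of −1.33. The PZ19b list mean of −0.08 ± 0.12 (SD, n = 3) lay close to the −0.19 of the untreated old library. Fetal and tumour-associated liver genes fell in 2 of 6 cases, 6 adjusted over the list alone, with Golm1 at −1.87 ± 0.29 and Scd2 at −1.24 ± 0.19 (camera adjusted p = 0.00197, and adjusted p = 0.612 with an estimated correlation). Proliferation genes fell in 1 of 8 cases, 6 adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.612 with an estimated correlation). The macrophage receptor Marco fell by 2.12 ± 0.23. Interferon response genes had a median of 0.17 and a camera adjusted p = 0.947.

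PZ19b in old mice raised 403 genes and lowered 356 by edgeR's test, 7.42% of those tested, with 61 and 100 past a 2-fold change and 2900 genes (28.4%, chance 10%) without overlap; 16 of 39 lists passed camera and none with an estimated correlation. The count hinged on single libraries: 41 without old replicate 2, 1233 and 1487 without old replicates 1 and 3, and 237, 419 and 227 without PZ19b replicates 1 to 3, with 1694 by DESeq2, 38 in a fit of the compared groups alone, 289 with the replicate number as a block and 780 for vehicle old against PZ19b mice of 26 months. Without TMM 172 rose and 943 fell, and the median of all genes shifted to −0.13. Called in all of these fits were Cyp2c54, Cyp2c23, Mup3, Ces3a, Acaca, Pgd, Gstm2, Gstm4, Nqo1 and Marco, while Slco1a1, Cyp2e1, Golm1, Scd2, Col5a2 and Sparc lost their calls without old replicate 2 (adjusted p from 0.0505 for Slco1a1 to 0.127 for Sparc) and in the fit of the compared groups alone. Col5a2 and Sparc also lost theirs without PZ19b replicate 1 (0.0667 and 0.0952) or 3 (0.0689 and 0.105), and Sparc without replicate 2 (0.0708). The main fit shares its estimate of the spread with the young libraries, which varied less than the old ones, so its p-values here draw on them.

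The aging and PZ19b changes were compared gene by gene to ask whether PZ19b moved genes back toward young levels. Across 10224 genes, which are not independent replicates, the slope of the PZ19b change on the aging change was −0.36 with r = −0.53. Simulations with an unchanged PZ19b group, in which young and old libraries were also drawn anew, gave a mean slope of −0.11 and a mean r of −0.21. Of these, 5 of 100 simulations had a slope as low. The covariance was −0.172 against a simulated mean of −0.0605, and 8 of 100 simulations had a covariance as low. Of the 2574 genes called with age, 79.9% had the opposite sign under PZ19b, where simulations averaged 59.7% and reached at most 79.6%. Among 434 genes called in both comparisons, 174 rose with age and fell with PZ19b and 247 did the reverse, against 51.1 and 43.6 for independent lists, while 8 rose in both and 5 fell in both. Simulations averaged 102 and 101 genes in these 2 opposite directions, and 11 and 9 of 100 had as many. The highest simulated counts were 1973 and 2174, and simulated replicates could be copies of each other, so these shares are rough. Nqo1, Pgd, Scd2 and Marco were among the genes that rose with age and fell with PZ19b, and Slco1a1 and Cyp2e1 among those that did the reverse. The old libraries enter both comparisons, and 3 of them are too few to leave 2 on each side of a split, so part of any excess may come from these shared controls.

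**Figure D3:**
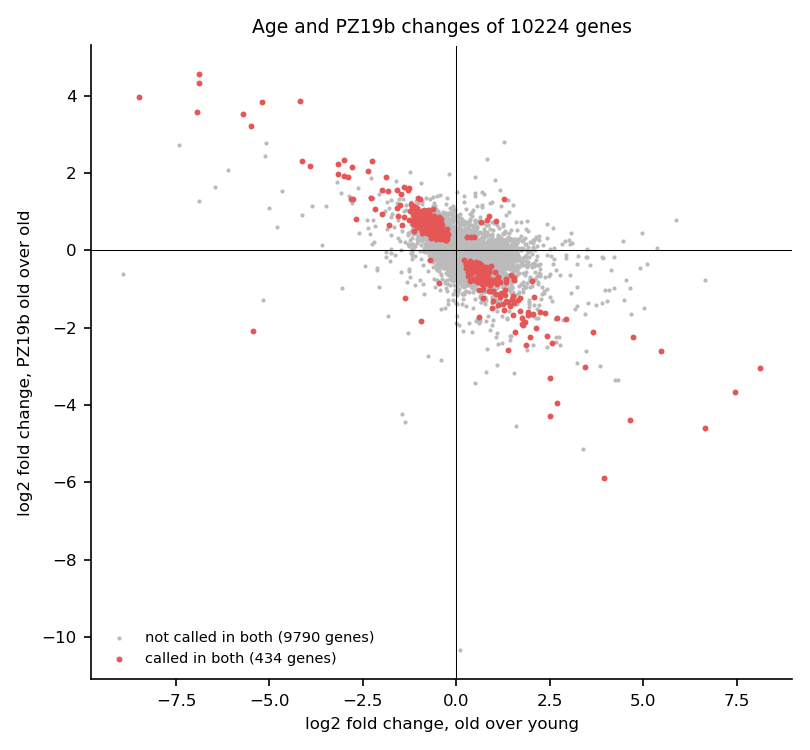
Log2 fold change with PZ19b in old mice against log2 fold change of old over young livers for 10224 genes, with the 434 genes called in both comparisons in red. Of these, 174 rose with age and fell with PZ19b and 247 fell with age and rose with PZ19b.

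The effect of losing Cisd2 in hepatocytes was read from hKO against f/f livers, both with vehicle. Acute phase genes, secreted by hepatocytes in inflammation, fell together. The serum amyloid genes Saa1, Saa2 and Saa4 changed by −6.42 ± 0.75, −7.60 ± 1.06 and −2.08 ± 0.20, Orm2 by −6.25 ± 0.87 and the siderophore-binding Lcn2 by −6.14 ± 1.15. Saa1 and Saa2 are near copies, so their split is uncertain. Metallothioneins Mt1 and Mt2 changed by −5.37 ± 1.18 and −6.97 ± 1.51, the chemokine Cxcl1 by −4.73 ± 0.51 and the cytokine signal inhibitor Socs3 by −2.35 ± 0.41. Of 24 measured acute phase response genes 22 fell, or 23 fell and 1 rose adjusted over the list alone, with a median of −1.60. The list's camera adjusted p was 3.10e-22, and adjusted p = 0.424 with an estimated correlation, and 18 members fell, with a median of −1.13, without the 3 f/f libraries in which these genes were highest.

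Kupffer cell markers moved with them: 7 of 12 fell, 11 adjusted over the list alone, with a median of −0.50 (camera adjusted p = 2.55e-07, and adjusted p = 0.424 with an estimated correlation). The f/f vehicle libraries were uneven on this list, with a mean log2 deviation of −0.02 in replicate 1 and 0.46 to 0.55 in the others. Without the same 3 f/f libraries the median of the Kupffer cells list was −0.40 and the camera adjusted p 0.000270, with no single member called by edgeR. Immediate early genes fell in 4 of 10 cases, 6 adjusted over the list alone, with Junb, an AP-1 subunit, at −1.67 ± 0.25 (camera adjusted p = 0.000118, and adjusted p = 0.424 with an estimated correlation). ER chaperones fell in 5 of 23 cases, 12 adjusted over the list alone, with the disulphide isomerases Pdia6 and Pdia3 at −0.67 ± 0.12 and −0.51 ± 0.10 and the calcium-binding chaperone Calr at −0.56 ± 0.12 (camera adjusted p = 5.64e-07, and adjusted p = 0.538 with an estimated correlation).

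Some lipid genes rose in the knockout. PPARα targets rose in 10 of 41 cases, 21 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 2.87e-11, and adjusted p = 0.424 with an estimated correlation). Fabp1, a fatty acid binding protein, rose by 0.82 ± 0.13 and the lipase Mgll by 0.57 ± 0.10, and Crat, a carnitine acetyltransferase, by 1.51 ± 0.14. Without the 3 f/f libraries 3 of the PPARalpha targets rose and the median was 0.14. Cholesterol synthesis and uptake genes rose in 5 of 25 cases, 9 adjusted over the list alone, including Hsd17b7 at 0.81 ± 0.15 and the sterol carrier Stard4 at 0.67 ± 0.13 (camera adjusted p = 3.46e-07, and adjusted p = 0.538 with an estimated correlation). Genes of fatty acid and triglyceride synthesis rose in 6 of 20 cases, 7 adjusted over the list alone, with the acyltransferase Gpam at 0.87 ± 0.13 and glucokinase, Gck, at 0.86 ± 0.14 (camera adjusted p = 4.93e-05, and adjusted p = 0.424 with an estimated correlation).

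For hKO against f/f with vehicle, edgeR called 276 genes higher and 425 lower, 7.06% of those tested, with 19 and 65 past a 2-fold change and 1386 genes (13.95%, chance 2.86%) without overlap; 14 of 39 lists passed camera and none with an estimated correlation. The count was 344 and 449 without f/f vehicle replicates 2 and 3, 410, 394 and 424 without hKO vehicle replicates 1, 2 and 4, 418 in a fit of the compared groups alone and 323 without the 3 f/f libraries with the highest acute phase genes.

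**Figure D4:**
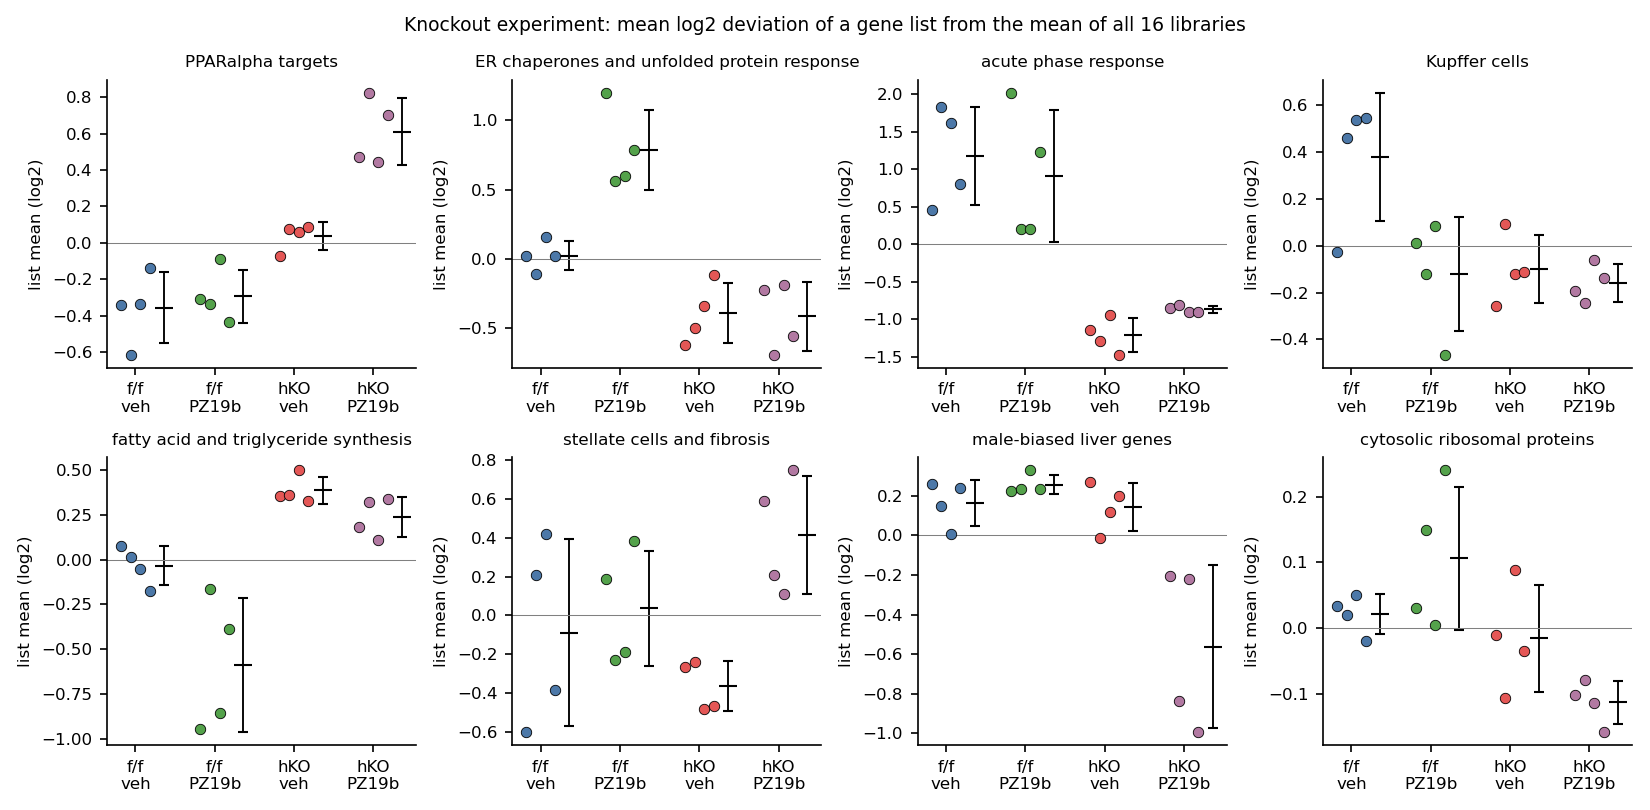
Mean log2 deviation of 8 gene lists in each library of the knockout experiment, with the group mean and SD (n = 4). For the acute phase list the lowest f/f library lies at 0.20 and the highest hKO library at −0.81.

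PZ19b in f/f livers raised genes of protein folding in the ER. Creld2, an ER stress-induced secreted factor, rose by 2.02 ± 0.27, the ubiquitin ligase Syvn1 by 1.36 ± 0.21, the chaperones Hspa5 and Hyou1 by 1.25 ± 0.22 and 1.27 ± 0.22, Pdia4 by 1.10 ± 0.17 and Sel1l, a partner of Syvn1 in ER-associated degradation, by 0.91 ± 0.11. Of 23 ER chaperones and unfolded protein response genes 16 rose, 21 adjusted over the list alone, with a median of 0.61. The camera adjusted p was 2.05e-16, and adjusted p = 0.610 with an estimated correlation, and 8 members rose without the 3 f/f libraries named above. Genes that fell included the water channel Aqp8 (−1.77 ± 0.15), Mmd2 (−1.66 ± 0.30), the NAD synthesis gene Nmnat3 (−1.55 ± 0.21), the kinase Camk1d (−1.27 ± 0.13) and the mineralocorticoid receptor Nr3c2 (−1.25 ± 0.13).

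Some lipogenic and macrophage genes fell in f/f livers. Of 20 genes of fatty acid and triglyceride synthesis 8 fell, 11 adjusted over the list alone, with a median of −0.50 (camera adjusted p = 3.84e-06, and adjusted p = 0.610 with an estimated correlation). Fatty acid synthase, Fasn, stood at −1.14 ± 0.26 and ATP citrate lyase, Acly, at −0.94 ± 0.21, and both lost their calls without the 3 f/f libraries, where 2 members of the list fell. Kupffer cells markers fell in 7 of 12 cases, 11 adjusted over the list alone, with the phagocytic receptor Timd4 at −0.82 ± 0.14 and Vsig4 at −0.53 ± 0.10 (camera adjusted p = 2.26e-06, and adjusted p = 0.610 with an estimated correlation), and in 2 cases without those libraries. Clock genes rose in 4 of 18 cases, 7 adjusted over the list alone, with the repressors Cry1 and Cry2 at 0.95 ± 0.16 and 0.82 ± 0.14 (camera adjusted p = 0.000235, and adjusted p = 0.610 with an estimated correlation). The labels give no hour of sampling, and the clock arm with Cry1 had a median of −0.04 and that with Dbp one of 0.54. PPARα targets had 1 of 41 rising and 0 adjusted over the list alone, and a camera adjusted p = 0.0276, which was 0.945 with an estimated correlation and, for the PPARalpha targets, 0.431 without f/f vehicle replicate 2, 0.0821 without replicate 3, 0.302 without f/f PZ19b replicate 3 and 0.993 without the 3 f/f libraries. Ribosomal protein genes and respiratory chain genes had medians of 0.08 each, near 0.01 without TMM, with camera adjusted p = 5.51e-05 for both, and adjusted p = 0.914 with an estimated correlation. The nuclear-encoded respiratory chain list lost its call without the 3 f/f libraries, at 0.0916.

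Across f/f livers PZ19b raised 425 genes and lowered 579, 10.1% of those tested by edgeR, with 17 and 35 past a 2-fold change and 1241 genes (12.5%, chance 2.86%) without overlap; 10 of 39 lists passed camera and none with an estimated correlation. The count was 516 without f/f vehicle replicate 2, 605 without the 3 f/f libraries and 285 in a fit of the compared groups alone, and without TMM 213 rose and 984 fell.

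In hKO livers PZ19b raised PPARα targets. Cyp4a14 and Cyp4a10, fatty acid hydroxylases that share close copies and so carry uncertain counts, rose by 3.23 ± 0.60 and 3.10 ± 0.42, the peroxisomal oxidase Acox1 by 0.66 ± 0.11, the thioesterase Acot4 by 1.46 ± 0.24 and the peroxisomal transporter Abcd2 by 1.84 ± 0.40. Of 41 PPARα targets 20 rose, 30 adjusted over the list alone, with a median of 0.37. The camera adjusted p was 9.03e-15, and adjusted p = 0.260 with an estimated correlation. Among ketogenesis genes 3 of 6 rose, 4 adjusted over the list alone, with the cleavage enzyme Hmgcl and the ketone dehydrogenase Bdh1 at 0.34 ± 0.07 each (camera adjusted p = 0.00561, and adjusted p = 0.260 with an estimated correlation). Lipid droplet and uptake genes rose in 4 of 14 cases, 9 adjusted over the list alone, with Cd36 at 1.36 ± 0.19 (camera adjusted p = 9.51e-05, and adjusted p = 0.260 with an estimated correlation). CAR and PXR targets, which handle drugs and bilirubin, rose in 7 of 14 cases, 11 adjusted over the list alone, with Ugt1a1 at 0.69 ± 0.10 and the efflux pump Abcc3 at 1.39 ± 0.23 (camera adjusted p = 1.66e-06, and adjusted p = 0.260 with an estimated correlation).

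Matrix genes also rose in hKO livers with PZ19b: 8 of 19 stellate and fibrosis genes, 15 adjusted over the list alone, with a median of 0.75 and Col3a1, a fibrillar collagen, at 1.57 ± 0.33 (camera adjusted p = 8.91e-08, and adjusted p = 0.357 with an estimated correlation). Fetal and tumour-associated genes rose in 4 of 5 cases by either adjustment, with the galectin Lgals1 at 1.51 ± 0.23 and the annexins Anxa2 and Anxa5 at 1.25 ± 0.20 and 0.81 ± 0.13 (camera adjusted p = 0.000204, and adjusted p = 0.260 with an estimated correlation). Male-biased genes fell in 9 of 17 cases, 11 adjusted over the list alone, with Elovl3, a fatty acid elongase, at −1.85 ± 0.24 and the complement gene C6 at −0.48 ± 0.10 (camera adjusted p = 8.91e-08, and adjusted p = 0.260 with an estimated correlation). The phosphatidate phosphatase Lpin1 fell by 1.65 ± 0.19. ER chaperones had a median of −0.09 and a camera adjusted p = 0.585.

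PZ19b in hKO livers raised 445 genes and lowered 336, 7.86% of those tested by edgeR, with 46 and 28 past a 2-fold change and 2154 genes (21.7%, chance 2.86%) without overlap; 15 of 39 lists passed camera and none with an estimated correlation. The count was 331 and 420 without hKO vehicle replicates 1 and 2, 339 and 329 without hKO PZ19b replicates 2 and 4, 1198 by DESeq2 and 1379 in a fit of the compared groups alone, and without TMM 1029 rose and 180 fell.

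Whether the PZ19b response depended on Cisd2 was tested with the interaction of treatment and genotype. Protein folding genes had a lower response in hKO than in f/f livers: the interaction was −2.26 ± 0.38 for Creld2, −1.67 ± 0.29 for Syvn1, −1.58 ± 0.32 for Hyou1 and −0.89 ± 0.16 for Sel1l. In the ER chaperones and unfolded protein response list 13 of 23 genes had a lower response, 19 adjusted over the list alone, with a median of −0.69 (camera adjusted p = 2.77e-11, and adjusted p = 0.443 with an estimated correlation), and 6 did without the 3 f/f libraries. PPARα targets had a higher response in hKO livers in 8 of 41 cases, or 13 with 1 lower adjusted over the list alone, with a median of 0.21. Cyp4a10 differed by 2.92 ± 0.59, the pantetheinase Vnn1 by 2.09 ± 0.44 and the thiolase Acaa1b by 1.32 ± 0.27 (list camera adjusted p = 0.000206, and adjusted p = 0.528 with an estimated correlation). The fatty acid transporter Cd36 differed by 1.85 ± 0.27, the adipogenic receptor Pparg by 1.54 ± 0.25, the lipogenic regulator Srebf1 by 1.95 ± 0.38 and the ketone enzyme Bdh1 by 0.47 ± 0.10.

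Fetal and tumour-associated genes had a higher response in hKO than in f/f livers in 4 of 5 cases by either adjustment, with Lgals1 at 2.25 ± 0.34 (camera adjusted p = 0.000206, and adjusted p = 0.417 with an estimated correlation). Kupffer cell markers had a median interaction of 0.46, with 8 of 12 higher adjusted over the list alone and none over all genes by edgeR (camera adjusted p = 0.00126, and adjusted p = 0.475 with an estimated correlation). Male-biased genes had a lower, more negative response in hKO livers in 6 of 17 cases, 8 adjusted over the list alone, among them C6 at −0.69 ± 0.15 (camera adjusted p = 9.74e-06, and adjusted p = 0.443 with an estimated correlation). Ribosomal protein genes had a median of −0.19, which was −0.03 without TMM, with 3 of 51 lower and 7 adjusted over the list alone (camera adjusted p = 5.40e-10, and adjusted p = 0.475 with an estimated correlation). By edgeR 474 genes had a higher and 324 a lower response in hKO livers, 8.03% of those tested, and 20 of 39 lists passed camera, none with an estimated correlation. The count was 516 without hKO vehicle replicate 4, 473 and 442 without hKO PZ19b replicates 2 and 4, 483 without the 3 f/f libraries, 1263 by DESeq2, and 1458 higher with 132 lower without TMM, where the median of all genes shifted by 0.15.

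With PZ19b in both genotypes, hKO and f/f livers differed in more genes than with vehicle. All 23 ER chaperone genes fell by either adjustment, with a median of −0.96, Creld2 at −2.77 ± 0.28, Syvn1 at −1.95 ± 0.21 and the chaperone Sdf2l1 at −1.98 ± 0.22 (camera adjusted p = 8.24e-18, and adjusted p = 0.298 with an estimated correlation). PPARα targets rose in 32 of 41 cases and fell in 1, or 33 and 1 adjusted over the list alone, with a median of 0.55. Cyp4a14 rose by 5.63 ± 0.73, Acot4 by 2.42 ± 0.25 and Pex19, a peroxisome biogenesis gene, by 0.56 ± 0.07 (list camera adjusted p = 1.85e-14, and adjusted p = 0.298 with an estimated correlation). Genes of ketogenesis and ketone export rose in 4 of 6 cases by either adjustment, with Bdh1 at 0.80 ± 0.07 and Hmgcl at 0.57 ± 0.07 (camera adjusted p = 0.0122, and adjusted p = 0.298 with an estimated correlation, or 0.0592 without TMM). Genes of fatty acid and triglyceride synthesis rose in 14 of 20 cases and fell in 1, or 16 and 1 adjusted over the list alone, with the desaturase Scd1 at 1.59 ± 0.26 (camera adjusted p = 6.53e-07, and adjusted p = 0.298 with an estimated correlation), and lipid droplet and uptake genes in 10 of 14 by either adjustment, with Pparg at 2.06 ± 0.18 (camera adjusted p = 5.20e-06, and adjusted p = 0.298 with an estimated correlation).

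Acute phase genes again fell, in 21 of 24 cases and 22 adjusted over the list alone, with Saa4 at −1.87 ± 0.20 and the interleukin receptor Il1r1 at −2.74 ± 0.35 (camera adjusted p = 5.02e-11, and adjusted p = 0.303 with an estimated correlation). Hepatocyte identity genes fell in 8 of 22 cases by either adjustment, with the transcription factors Hnf4a at −0.74 ± 0.12 and Foxa3 at −1.12 ± 0.18 (camera adjusted p = 0.00795, and adjusted p = 0.298 with an estimated correlation). Ribosomal protein genes fell in 43 of 51 cases, 47 adjusted over the list alone, with a median of −0.22, and in 3 cases with a median of −0.05 without TMM (camera adjusted p = 9.40e-13, and adjusted p = 0.436 with an estimated correlation). Kupffer cell markers had a median of −0.03, which was 0.14 without TMM, and a camera adjusted p = 0.823. EdgeR called 1513 genes higher and 1547 lower, 30.8% of those tested, with 130 and 154 past a 2-fold change and 3093 genes (31.1%, chance 2.86%) without overlap. Without TMM 3745 rose and 605 fell as the median of all genes shifted by 0.17, and 15 of 39 lists passed camera, none with an estimated correlation.

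**Figure D5:**
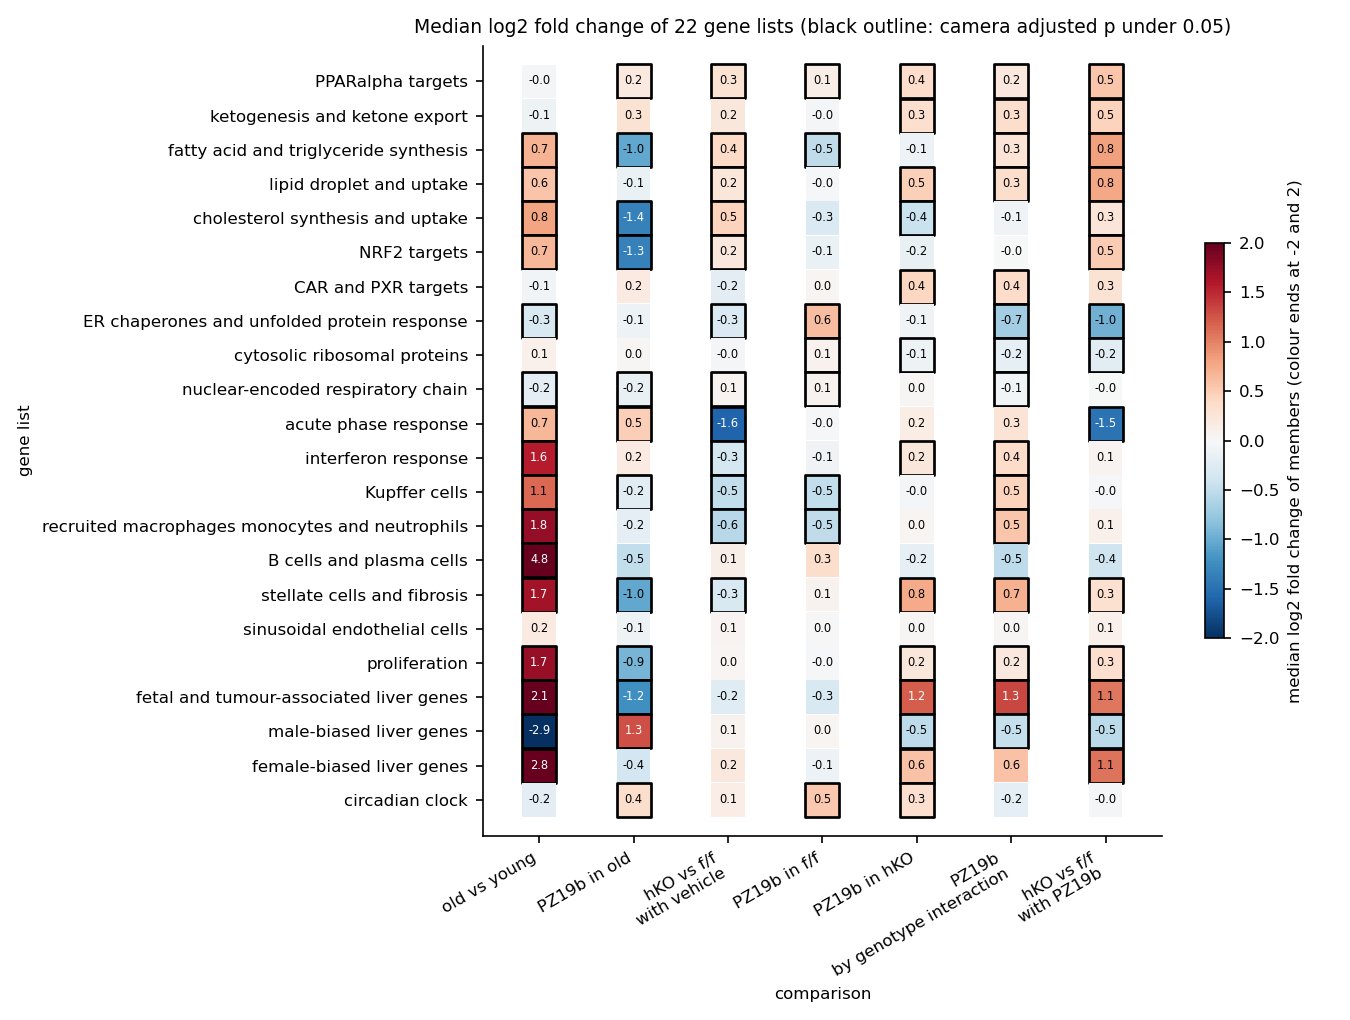
Median log2 fold change of 22 gene lists in the 7 comparisons, with an outline where camera's adjusted p passed 0.05 at the preset correlation. ER chaperones have a median of 0.61 for PZ19b in f/f, −0.09 for PZ19b in hKO and −0.96 for hKO against f/f with PZ19b, and respiratory chain genes one of −0.19 for old against young that became 0.11 without TMM.

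Reversal was also computed for the knockout change. The slope of the PZ19b change in hKO livers on the knockout change was −0.19 with r = −0.22 across 9935 genes, beside a simulated mean slope of −0.08 and r of −0.19, and 8 of 100 simulations had a slope as low. The covariance of −0.0190 compared with a simulated mean of −0.0101, which 16 of 100 simulations reached. Of 701 genes called in the knockout 70.5% had the opposite sign under PZ19b, against a simulated 61.8% that 16 of 100 simulations reached. Among 102 genes called in both, 42 rose and then fell and 42 fell and then rose, against 9.33 and 19.04 for independent lists, which leave out the shared hKO vehicle libraries. Another 14 rose in both and 4 fell in both. Those that rose in both included the PPARα targets Acot1, Cpt1a, Decr1 and Aldh3a2 and the ketogenesis genes Bdh1 and Hmgcl. Simulations averaged 4.58 genes that rose and then fell and 5.33 that fell and then rose, and 2 of 100 had as many in either direction. The simulated fits left out the f/f PZ19b libraries, which the real fit held, and the groups in a fit alter the calls. Simulated counts and shares of called genes are therefore not like for like with the real ones. With the 4 hKO vehicle libraries split 2 and 2, the slope over 6 splits averaged −0.09, from −0.15 to 0.01, and the covariance −0.00965. These splits called at most 3 genes that rose and then fell, 8 that fell and then rose and 13 that moved the same way in both.

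PZ19b responses were then set against each other between experiments, which share no libraries. Across 9707 genes, r was 0.149 (rho 0.144) between PZ19b in old and in f/f livers, 0.038 (rho 0.056) between old and hKO livers, and −0.162 (rho −0.191) between old against young and hKO against f/f. PZ19b in f/f and in hKO livers gave r = 0.061 (rho 0.050) across 9935 genes. Correlations as large arose in 62, 220 and 102 of 306 pairs of other splits and in 744 of 1156 for the last pair. Between old and hKO livers r was −0.04 without old replicate 1 and −0.02 without old PZ19b replicate 2. Called in both old and f/f livers under PZ19b were 27 genes that rose and 35 that fell, against 16.8 and 19.9 for independent lists, while 11 rose in old and fell in f/f livers and 13 did the reverse, against 23.0 and 14.6. Genes that rose with age and fell in the knockout numbered 122, against 52.7, and 46 did the reverse, against 30.2. In that pair 21 rose in both, against 34.6, and 46 fell in both, against 46.1. Under PZ19b, 45 genes fell in both f/f and hKO livers, against 19.6, and 24 rose in both, against 19.04, while 9 rose in f/f and fell in hKO livers, against 14.4, and 24 did the reverse, against 25.9. Between old and hKO livers 21 rose in both, against 17.4, and 12 fell in both, against 11.5, while 20 rose in old and fell in hKO livers, against 13.2, and 12 did the reverse, against 15.1.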

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

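The tests of macrophage share, hepatocyte share, vehicle and sequencing depth below were chosen only after the results they bear on were seen.

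Among 188 sets of 4 libraries examined for a library far from the rest, 9 held one, where chance alone marks about 1 in 20, or 9.4. In f/f vehicle livers, the mean log2 deviation of sex chromosome genes was 0.1326 in replicate 1 (others −0.03 to −0.02), that of Kupffer cell markers −0.02486 in replicate 1 (others 0.46 to 0.55) and that of iron handling genes −0.1531 in replicate 3 (others 0.01 to 0.02). In f/f PZ19b livers, replicate 3 stood apart for MHC class II genes (0.3236, others −0.45 to −0.36), male-biased genes (0.3284, others at 0.23) and adipocyte genes (−0.03492, others −0.36 to −0.32), replicate 1 for periportal genes (−0.2682, others −0.06 to −0.02) and replicate 2 for Cisd2 (27.61 CPM, others 24.8 to 25.1). In hKO PZ19b livers replicate 1 stood apart for integrated stress response targets (−0.09225, others −0.22 to −0.21).

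The PZ19b response differed between genotypes, by the interaction test of edgeR, for 28 of the 43 genes named for PZ19b in f/f or hKO livers, against 8.03% of all genes tested. Nearly all of the 43 were chosen for a large response in 1 genotype, an estimate that also enters the interaction, so a high share is built in and is not evidence of a wider genotype difference. The response was lower in hKO livers for the ER genes Creld2 (−2.26), Syvn1 (−1.67), Hyou1 (−1.58), Hspa5 (−1.39), Manf (−1.43), Sdf2l1 (−1.12) and Pdia4 (−1.02), and for Fndc3b (−0.88) and Hspb1 (−0.95). It was also lower for Moxd1 (−4.71), Adgrf1 (−3.04), Gtpbp4-ps1 (−2.65), Mup11 (−2.05), Serpina1e (−1.79) and Elovl3 (−1.21), of which the pseudogene, Mup11 and Serpina1e have near copies and uncertain counts. It was higher in hKO livers for Cyp4a14 (3.82), Cyp4a10 (2.92), Abcd2 (3.06), Dsg1c (2.10) and Wipf3 (1.80), and for genes named for their fall in f/f livers: Cyp2c38 (2.87), Adam11 (2.39), Mmd2 (1.95), Nmnat3 (1.86), Aqp8 (1.65), Pik3c2g (1.09), Shank2 (0.92) and Nr3c2 (0.82). For the ER gene Derl3 the estimates were 1.71 in f/f and 1.61 in hKO livers, with an interaction of −0.10 ± 0.70 (edgeR adjusted p = 0.952). That SE is too wide to show an equal response.

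Other splits of the same libraries were counted for each comparison. With 35 splits, the real one alone (1 of 35) gave its count for hKO against f/f with vehicle (701, highest other 4), PZ19b in f/f (1004, highest other 219), PZ19b in hKO (781, highest other 1) and hKO against f/f with PZ19b (3060, highest other 1), and 1 of 100 splits did for the interaction (798, highest other 186). A split that mixes the groups puts any group difference into the spread, which lowers its count. The shares of 35 splits therefore make chance less likely without excluding it. The splits for the interaction reassigned treatment within each genotype, so a PZ19b effect common to both genotypes also lowered their counts. Their share therefore decides nothing about whether the response differs with genotype. The 10 splits of old against young (2574, highest other 0) and of PZ19b in old mice (403 rose and 356 fell, highest other 0) are too few for a share under 0.05.

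Acute phase genes were lower in hKO than in f/f livers. A few f/f libraries as the whole source are argued against, since 18 of 24 members were still called lower without the 3 f/f libraries where they were highest. That fit kept only replicates 1 and 4 of the f/f vehicle group. Over both treatments the lowest f/f library, at a list mean of 0.20, lay above the highest hKO library, at −0.81. Macrophage and neutrophil markers, 16 in all, had a median of −0.50 against −1.60 for acute phase genes, a gap of 1.10. This gap decides nothing about fewer such cells in hKO livers, because hepatocytes make the acute phase transcripts and a signal from those cells sets no size for their fall. Kupffer cells markers fell in 7 of 12 cases (camera adjusted p = 2.55e-07, and adjusted p = 0.424 with an estimated correlation), so this explanation stays open. The loss of Cisd2 in hepatocytes and any difference in inflammatory state between the cohorts stay open.

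Collagen, proliferation and fetal liver genes were higher in the 2 vehicle old libraries than in the untreated one, whose list means lay above young by 0.58, 0.57 and 0.87. A lower share of hepatocytes as the whole source is argued against, because endothelial markers rose 0.17 over young in the vehicle libraries and stellate markers 2.15, a difference of −1.98 beside an SD of 0.90 between old libraries. A smaller loss of hepatocytes is not excluded: in the vehicle libraries hepatocyte identity genes lay −0.57 from young, cholangiocyte markers 0.62 and Kupffer markers 1.06. The vehicle itself stays open: the untreated library lay nearer to young on 3 of 3 lists, but a single untreated old library has no spread, and vehicle and individual cannot be told apart. Age, and differences between old mice, stay open as well.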

How the results depend on the processing

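The fits on whole-part counts, on library totals without TMM, of vehicle old against PZ19b mice of 26 months and without 3 f/f libraries were chosen after the data were seen. Of 532 named gene results, 418 were called, and 178 of these lost the call in at least 1 alternative, 157 in a planned one. Same direction and side of the threshold held for 531 with whole-part counts, 528 with RLE factors, 479 with the replicate block and 474 without TMM. By DESeq2 470 held, 60 gained a call and 2 lost it. The fit without the low count filter repeated the main one for all 532, since the filter kept every gene, and so tests nothing. Fits of the compared groups alone and without the 3 f/f libraries covered only part of the 532 results. The former kept 356, lost 79 calls and gained 6. The latter kept 217, lost 67 calls, gained 3 and changed 2 in sign. Leaving out single replicates lost 604 calls and gained 90, summed over replicates. With library totals of 20.7 M to 27.8 M, replicates differed by at least 15.5 times counting noise (chi-square per degree of freedom), so depth limits mainly weakly expressed genes. Changes of 1.5-fold in groups of 3 were recovered in 23.9% of simulated cases, in which few genes changed and all groups had the same spread. Genes under the tables' floor were not analysed here. Where no cause is named, the cause was not tested.

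Without TMM the called genes numbered 4415 for old against young, 1209 for PZ19b in hKO and 1590 for the interaction, as the reference level itself moves. There Cisd2 changed sign in old against young (0.2141), PZ19b in f/f (−0.0209), PZ19b in hKO (0.0225) and the interaction (0.0433), Ppara in the interaction (0.0947) and Cox7a2 in the interaction (0.0026), and Hmgcs2 stood at 0.6746 in old mice, no longer called, and at 0.4464 in hKO, called. DESeq2 called 1694 genes for PZ19b in old, 1198 in hKO and 1263 for the interaction, with Hmgcs2 in hKO (0.3666) and Ppara in old (0.8658) passing. In fits of the compared groups alone, which use only the spread of those groups, 38 genes were called for PZ19b in old, 418 for hKO against f/f with vehicle, 285 for PZ19b in f/f and 1379 in hKO. Chi-square per degree of freedom of replicate pairs ran from 15.5 to 26.2 in young, 64.0 to 253 in old and 70.1 to 110 in old PZ19b livers. The main fit shares its spread over these groups, so its p-values for PZ19b in old draw on the less variable young libraries. Hmgcs2 in old (0.8046) and Ppara in f/f (0.561) lost their calls there, and Hmgcs2 in hKO (0.3679) passed. Vehicle old against PZ19b mice of 26 months gave Cisd2 at 0.0604, Hmgcs2 at 0.6237, not called, and Ppara at 0.6375, called. Without the 3 f/f libraries 323 genes were called for hKO against f/f with vehicle, 605 for PZ19b in f/f and 483 for the interaction, and Hmgcs2 (−0.0022), Cd9 (0.3278) and Col6a3 (0.0370) changed sign in hKO against f/f with vehicle. With camera's estimated correlation 0 lists passed in each of the 7 comparisons, with lowest adjusted p of 0.333, 0.288, 0.424, 0.610, 0.260, 0.417 and 0.298 in the order old against young, PZ19b in old, hKO against f/f with vehicle, PZ19b in f/f, PZ19b in hKO, interaction and hKO against f/f with PZ19b.

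Leaving out single replicates gave 1135 to 3415 genes for old against young, 41 to 1487 for PZ19b in old, 344 to 776 for hKO against f/f with vehicle, 516 to 1138 for PZ19b in f/f, 329 to 669 in hKO, 442 to 876 for the interaction and 2317 to 3023 for hKO against f/f with PZ19b. For old against young Hmgcs2 ran from −0.5356 to −0.2082 and Ppara from −0.7337 to −0.1514. For PZ19b in old mice Cisd2 ran from −0.0710 to 0.0281, Hmgcs2 from 0.6539 to 0.9813 and Ppara from 0.5905 to 1.1728. Ppara ran from 0.4696 to 0.6537 for PZ19b in f/f, from 0.4058 to 0.5754 for PZ19b in hKO and from −0.1536 to 0.0314 for the interaction, and Hmgcs2 from 0.2989 to 0.4278 for hKO against f/f with PZ19b. Cd9 ran from −0.2183 to 0.0778 in hKO against f/f with vehicle (Cd9, hKO vs f/f with vehicle), Cyp17a1 reached −0.7142 at its lowest (Cyp17a1, PZ19b in hKO), and r between PZ19b in old and in hKO ran from −0.0395 to 0.1118. Over all alternatives, the highest values for old against young were −0.0583 for Hmgcs2 and −0.0992 for Ppara.

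The values gave no clear sign that replicate numbers pair the libraries: in no comparison did every pair of same-numbered libraries correlate above 0.1, with r from −0.36 to 0.22. The labels do not say whether the numbers pair mice, so pairing is not excluded. With the replicate number as a block, which spends degrees of freedom, PZ19b in old called 289 genes, Hmgcs2 there stood at 0.83 without its call, and Cyp17a1 changed sign (−0.0825 for the result Cyp17a1, PZ19b in hKO). At most 2 libraries of a comparison correlated best with their own number.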

Other observations

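The test of the hour of the day below was set out before its result was seen, and that of depth only afterwards.

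Some gene groups were not described above. In old livers 5 of 19 bile acid synthesis and transport genes fell, 7 adjusted over the list alone, with a median of −0.39 and the uptake transporter Slco1b2 at −0.76 ± 0.15 (camera adjusted p = 0.00334, and adjusted p = 0.467 with an estimated correlation). Immediate early genes rose in 4 of 11 cases with a median of 0.63, among them Klf6 at 1.55 ± 0.17 and Jun at 1.10 ± 0.19 (camera adjusted p = 0.0126, and adjusted p = 0.467 with an estimated correlation). Without TMM the adjusted p of the immediate early genes list was 0.135. PZ19b in old mice gave cholangiocyte markers a median of −0.79, with 3 of 7 falling, or 4 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0476, and adjusted p = 0.612 with an estimated correlation). For cholangiocytes the list call was lost without old replicate 2 or 3 (0.0527 and 0.181) or PZ19b replicate 2 (0.115), with the replicate number as a block (0.0592) and without TMM (0.148).

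In hKO livers PZ19b moved clock genes both ways, with 6 of 18 rising and 2 falling, or 8 and 2 adjusted over the list alone. Cry1, a repressor, rose by 0.83 ± 0.16 and the nuclear receptor Rorc by 1.13 ± 0.21, while Nr1d1 fell by 1.09 ± 0.23 (list camera adjusted p = 0.0235, and adjusted p = 0.510 with an estimated correlation). The circadian clock list lost its call without hKO vehicle replicate 1 or 2 (0.0771 and 0.0570) and without TMM (0.135). In the interaction, MHC class II genes had a median of 0.70, with 3 of 5 higher adjusted over the list alone (camera adjusted p = 0.00824, and adjusted p = 0.475 with an estimated correlation). The camera adjusted p of the MHC class II presentation list was 0.0547 without TMM.

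Clock, cholesterol and lipogenic genes were out of line in the untreated old library, whose clock list mean was −1.36 against 0.02 and 0.16 in the vehicle old libraries. Depth is argued against, as its total of 22.1 M expected counts lay within the 21.6 M to 27.5 M of the other 8. A hypothesis is that this liver was taken at another hour of the day: the 3 measured genes of one clock arm had a median deviation of 0.97 and the 9 of the other −1.93, a difference of 2.90, with Nfil3 at 1.60 and Dbp, Ciart and Bhlhe41 at −4.74, −3.58 and −3.38. Such an hour may also set part of its cholesterol list mean of 1.61, which enters the fall of these genes under PZ19b. In the PZ19b comparisons the same arms had medians of −0.04 and 0.54 in f/f, −0.47 and 0.26 in hKO and −0.32 and 0.58 in old livers, so an hour that differed between groups stays open there too. Feeding state was not tested, the labels give no hour, and the individual mouse stays open as the biological explanation.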
